A study of Mus musculus with 150 samples.

How the data were processed

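Genomic DNA of 150 single cells from 3 microdissected lung tumours of 1 mouse was sequenced, 50 cells per tumour, and the tables held 1 column per cell. Reads were aligned with BWA 0.7.17 to GRCm38, per the submitters' processing notes. Per the file headers, the genome was divided into 5331 bins on the 19 autosomes, X and Y, each listed with the genes it overlaps. The median length of all these bins was 500 kb. The deposited depth table gives the coverage signal of each bin, the mean number of reads over each base, and 99.8% of its values times the bin length were whole numbers of bases within 0.1. The deposited log2 ratio table gives a log2 value per bin and cell, already centred near 0 in each cell and corrected by an offset that varies by bin and cell. The tool and reference behind that log2 ratio are not given in the sources used here. The deposited weight table gives a score between 0 and 1 for each bin, the same in all cells, whose making is likewise not given in the sources used here. How the cells were sorted and amplified is also not given in the sources used here, and the RNA sequencing of cells from the same tumours, which the labels mention, was not used here.

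All filters, thresholds of the gain and loss calls, gene lists, the rule for named items and all alternatives but the removal of bins alike in all tumours and the mode centring of the share of flat autosome levels were fixed before the data were examined. The bounds for an intermediate level, the narrower windows and the scan for departures of single tumours came after values were seen. A bin was kept if it lay on an autosome or X and had depth and a finite log2 ratio in at least 80% of the cells, which left 5149 bins, 4806 on autosomes and 343 on X, and left out 181 Y bins and 1 other. Noise of a cell was 1.4826 times the median absolute difference between neighbouring autosomal bins, divided by the square root of 2. A cell was kept if at least 80% of the autosomal bins had depth and its noise was at most the median plus 3 scaled median absolute deviations, a limit of 0.267. This left out 3 cells of T1, 2 of T7 and 0 of T9. Each kept cell was centred on the median of its autosomal bins. A doubling of the whole genome therefore cannot be seen, and a level states copy number relative to the rest of the cell.

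A chromosome was called gained in a cell when the median of its bins was at least 0.32, the log2 of 2.5 copies over 2, and lost at or under -0.42, the log2 of 1.5 copies over 2. Chromosomes were also divided into segments by least-squares optimal partitioning with a penalty of 3 times the natural log of the number of bins for each break and segments of at least 5 bins and 10 Mb, and segment means were called with the same thresholds. A region is a run of bins inside such a segment in at least 20% of a tumour's cells. A count of cells for a region in its own tumour is that at the bin with the highest share, and a count for 2 regions together is of cells with most of each region called. Coordinates are those of the files, on GRCm38, and gene positions came from a RefSeq table of GRCm38.p6. Each of the 53 fixed genes was given the segment mean of the bin holding its middle. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9.

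Named chromosomes are those called in at least 20% of the cells of a tumour, and named regions are those of under 80% of their chromosome, at most 10 per tumour. Named genes are the engineered or recombined loci, of which 1 result is not reported here, and then the genes of the fixed lists in a called segment in at least 20% of the cells of a tumour. The lists held 16 oncogenes, 16 tumour suppressors, 7 genes of alveolar type 2 identity and 11 of plasticity and mesenchymal state. The narrower windows on chromosomes 8 and 13 and the genes named in them were chosen after their values were seen. Windows were runs of at least 5 bins, with gaps of up to 2, in which at least 10% of a tumour's cells reached a log2 ratio of 1 in a running median over 3 bins.

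Every sample is 1 cell and every group 1 tumour of the same animal, so cells are not replicates of a condition and no test was made between tumours. Shares of cells carry exact Clopper-Pearson 95% intervals for counting error, and where no cell was counted the limit of 3 cells of the total was given. Correlations of noise with depth were tested with 2-sided permutation tests of 100000 resamples, adjusted by Benjamini-Hochberg over 8 relations. No pair of cells had identical columns, and the highest correlation between 2 cells was 0.868. How wells with more than 1 cell were treated is not given in the sources used here, and no doublet caller was run.

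The median depth per base was 0.0354 in T1, 0.0250 in T7 and 0.0213 in T9. Reads per bin were not used here. The segmentation and calling were tested on simulated data made by planting changes on the residuals of real cells, with 100 cells for each tumour and step size and all 5149 bins. Whole chromosomes were recovered in 100% of cases at full steps of 0.58 and -1 and at reduced steps of 0.40 and -0.60. All planted steps lay past the call thresholds, so this recovery was largely fixed by the design. Levels at or under a threshold, such as the 0.27 of chromosome 6 in T9, were not planted, and their recovery was not tested. Segments of 30 Mb were recovered in 100% at full steps. At the reduced steps, gained segments were recovered in 92.5%, 95.8% and 94.5% of cases with the noise of T1, T7 and T9, and lost segments in 97.9%, 100% and 100%. No other chromosome was called, and at most 0.124% of other bins were. Residuals have the segment means removed, so these data leave out slow waves along the genome. The recovery rates are therefore upper estimates, and the rates of other calls are lower estimates. The simulated cells were flat apart from the planted changes, so centring of cells with many changed chromosomes was not tested.

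The alternatives were all cells, a stricter noise limit of 1 median absolute deviation, all bins with a finite ratio, the log2 of depth over the cell's median in place of the deposited ratio, and centring on the mean or the mode. Others were the deposited weights in a mean over bins, looser thresholds (0.20 and -0.25), stricter thresholds (0.45 and -0.70), a penalty factor of 10, segments of at least 5 or 20 Mb, regions in at least 10% of cells, correlation over bins smoothed by a running median of 11, and the standard deviation of all bins as the noise. Removal of 32 bins that departed by at least 0.30 in the same direction from a running median of 101 bins in all 3 tumours was added after seeing the data. An earlier form of it without the running median also took bins of the chromosome 6 gain that the tumours share, and was replaced for that reason.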

Results

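DNA copy number was measured in single cells of 3 lung tumours, T1, T7 and T9, that were dissected from 1 mouse 30 weeks after tumour induction. The mouse belonged to a model of lung adenocarcinoma in which Cre recombinase deletes parts of both Trp53 alleles and turns on a reporter at the Rosa26 locus in lung epithelium. The labels give alveolar type 2 cells of lung tissue as the source. Each tumour contributed 50 cells, and 145 of the 150 cells passed the filters, 47 from T1, 48 from T7 and 50 from T9. The sequenced bases per cell had a median of 94.0 Mb in T1 (range 20.5 to 170.1), 69.3 Mb in T7 (0.241 to 140.3) and 56.7 Mb in T9 (43.3 to 82.1). Every group was 1 tumour (n = 1), so tumours were described side by side without a test, and each interval given for a share of cells is an exact Clopper-Pearson 95% interval that covers counting error only. Levels are log2 ratios relative to the typical autosomal level of the same cell, given as the median over cells with the SD over cells.

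The first question was which whole chromosomes each tumour had gained or lost. In T1, chromosome 4 was lost in 45 of 47 cells (95.7%, 85.5 to 99.5) at a level of -0.69 (SD 0.10), and chromosome 9 was lost in 44 of 47 cells (93.6%, 82.5 to 98.7) at -0.56 (SD 0.08). Chromosome 6 was gained in 37 of 47 T1 cells (78.7%, 64.3 to 89.3) at 0.39 (SD 0.12). T7 shared the gain of chromosome 6, in 37 of 48 cells (77.1%, 62.7 to 88.0) at 0.38 (SD 0.13), and carried a gain of chromosome 2 in 34 of 48 cells (70.8%, 55.9 to 83.0) at 0.39 (SD 0.17). In T9, chromosome 9 was called lost in 39 of 50 cells (78%, 64.0 to 88.5) at -0.46 (SD 0.12), and chromosome 6 was called gained in 11 of 50 cells (22%, 11.5 to 36.0) at 0.27 (SD 0.14).

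The same chromosomes were then counted in the other tumours. Loss of chromosome 4 was called in 0 of 48 T7 cells, which allows a share of up to 6.25%, and in 3 of 50 T9 cells (6%, 1.25 to 16.5). Gain of chromosome 2 was called in 0 of 47 T1 cells and 0 of 50 T9 cells, which allows shares of up to 6.38% and 6%. Chromosome 9 was lost in 2 of 48 T7 cells (4.17%, 0.509 to 14.3). Chromosome 10 was lost in 13 of 47 T1 cells (27.7%, 15.6 to 42.6), in 8 of 48 T7 cells (16.7%, 7.48 to 30.2) and in 0 of 50 T9 cells, which allows up to 6%. No other autosome, and not X, reached 20% of the cells of any tumour.

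**Figure D1:**
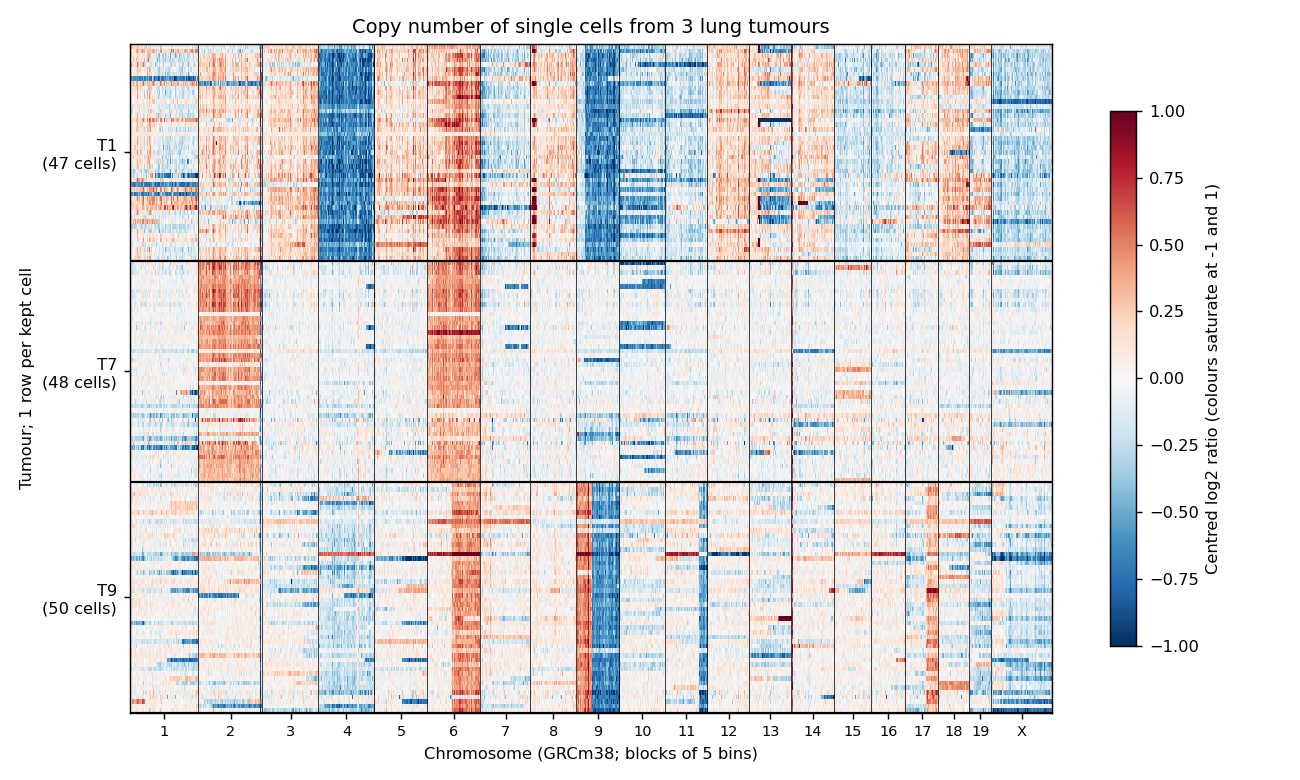
Centred log2 ratio of 145 single cells (1 line per cell, grouped by tumour, 47, 48 and 50 cells) along the autosomes and X in blocks of 5 bins, red for higher and blue for lower values. T1 shows blue bands on chromosomes 4 and 9 and a red band on chromosome 6, T7 shows red bands on chromosomes 2 and 6, and chromosome 9 of T9 changes from red to blue within the chromosome.

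The observed steps were smaller than the -1 and 0.58 that 1 or 3 copies against 2 would give, so the shares depended on the thresholds. Under stricter thresholds (0.45 and -0.70), loss of chromosome 4 was called in 40.4% of T1 cells and losses of chromosomes 9 and 10 in 2.13% each. Loss of chromosome 9 was then called in 0% of T9 cells, and gain of chromosome 2 in 16.7% of T7 cells. Gain of chromosome 6 was called in 25.5%, 20.8% and 4% of T1, T7 and T9 cells with these thresholds. The gain of chromosome 6 was also called in 38.3% of T1 and 8% of T9 cells with centring on the mode, in 10% of T9 cells with a weighted mean over bins and in 82% of T9 cells with looser thresholds. The chromosome 9 call in T9 rests on a median over a chromosome of which 43.8 Mb near the start was gained, and it was made in 0% of the cells with a weighted mean over bins and in 48% with the ratio taken from depth.

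**Figure D2:**
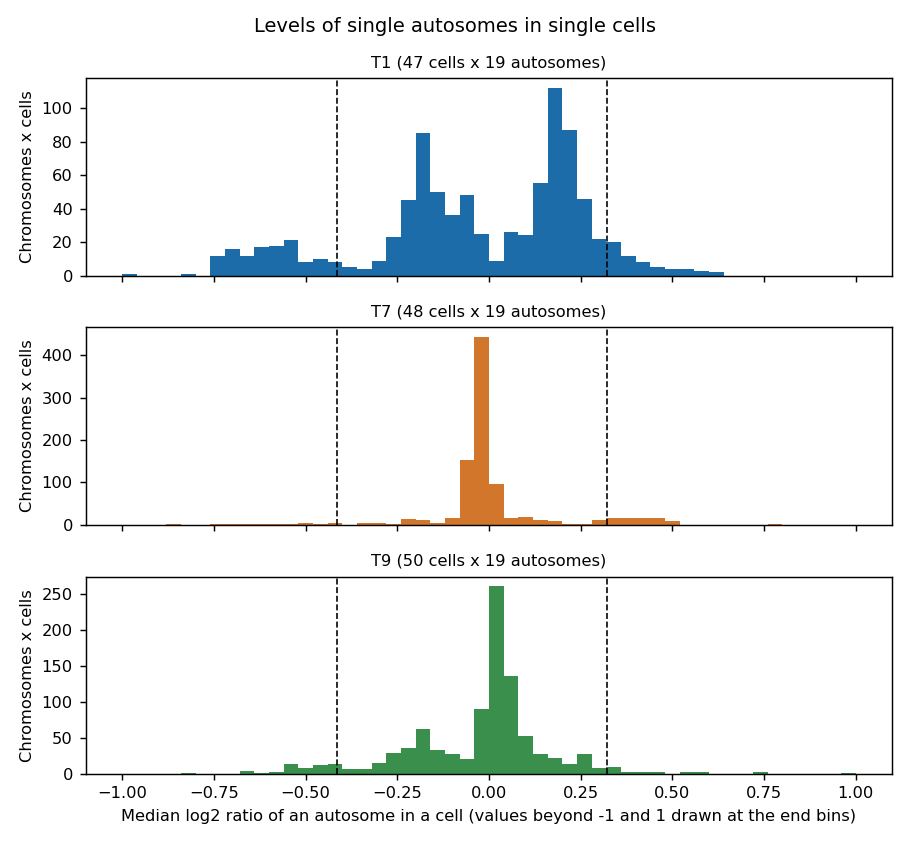
Histograms of the median log2 ratio of each of 19 autosomes in each cell, 1 panel per tumour (47, 48 and 50 cells), with dashed lines at the gain and loss thresholds. Values between a flat level and the thresholds made up 61.3% of the T1 values, 8.77% of the T7 values and 30.5% of the T9 values. The bounds of the flat level, -0.12 and 0.12, were chosen after the data were seen.

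Segmentation then gave the regions within chromosomes. T9 carried both directions on chromosome 9. Its start, 3491634 to 47252283, was gained in 45 of 50 cells (90%, 78.2 to 96.7) at 0.46 (SD 0.15), and the adjoining 47252284 to 124495110 was lost in 47 of 50 cells (94%, 83.5 to 98.7) at -0.60 (SD 0.13). T1 had a loss of chromosome 9 from 28342824 to 124495110 in 46 of 47 cells (97.9%, 88.7 to 99.9) at -0.63 (SD 0.09), so the break lay at another position than in T9. The gain of chromosome 6 in T9 covered its distal part, 69719313 to 149586546, with 42 of 50 cells (84%, 70.9 to 92.8) at 0.42 (SD 0.16). The region spanned the whole chromosome in T1 and T7, but in T1 the same distal part lay at 0.49 (SD 0.14), with 37 of 47 cells, while proximal Met and Braf lay at 0.20, and in T7 the distal part and both genes lay at 0.38.

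The other named regions of T9 lay on chromosomes 11, 17 and X, beside the start of chromosome 14. The end of chromosome 11, 99034872 to 121982543, was lost in 44 of 50 cells (88%, 75.7 to 95.5) at -0.54 (SD 0.21), against a level of -0.14 in T1 and -0.02 in T7. The end of chromosome 17, 59285304 to 94887271, was gained in 23 of 50 cells (46%, 31.8 to 60.7) at 0.31 (SD 0.15), and in none of the 47 T1 or 48 T7 cells. The end of X, 123193139 to 170881299, was lost in 12 of 50 cells (24%, 13.1 to 38.2) at -0.20 (SD 0.20), and T1 had the same level of -0.20 (SD 0.13) there, with 3 of 47 T1 and 2 of 48 T7 cells past the threshold.

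**Figure D3:**
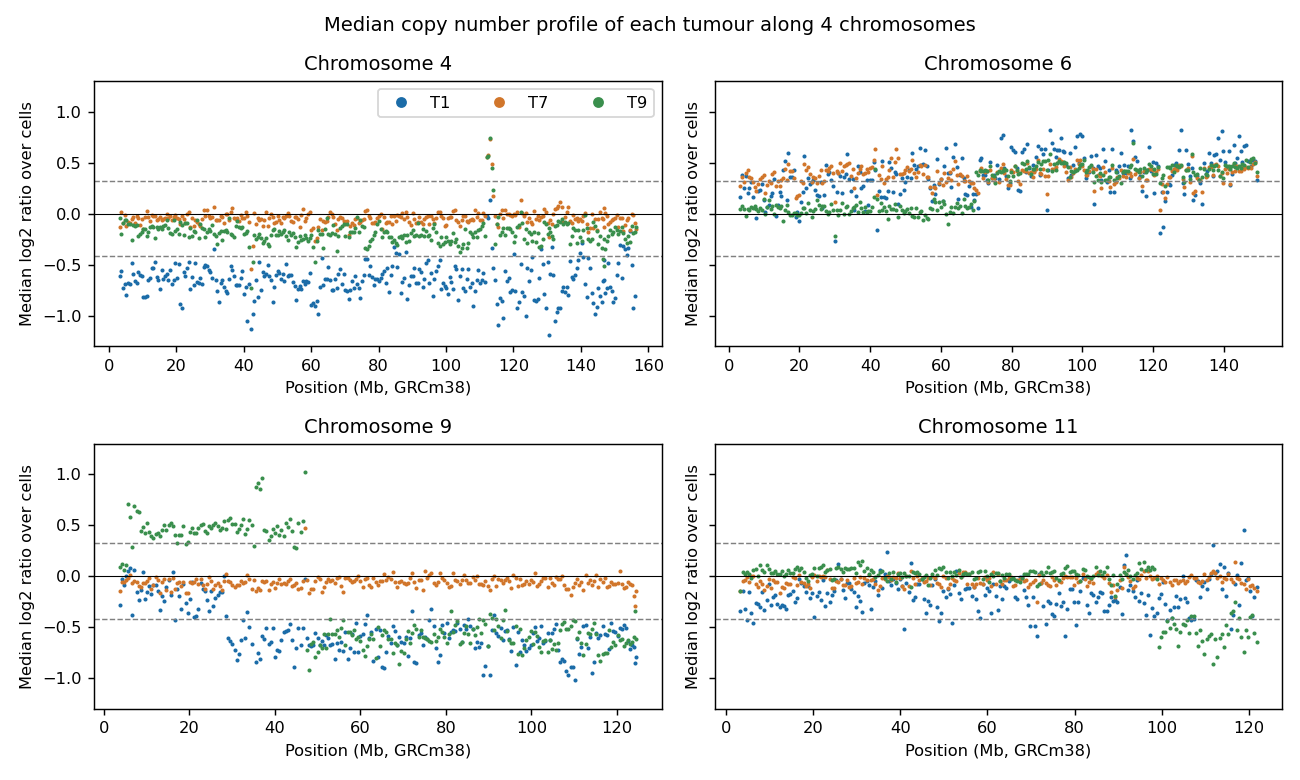
Median log2 ratio over the cells of each tumour (47, 48 and 50 cells) in every kept bin along chromosomes 4, 6, 9 and 11, against position in Mb, with dashed lines at the thresholds. The T9 points on chromosome 9 step from about 0.46 to about -0.60, and those on chromosome 6 rise to 0.42 in the distal part.

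In T1, further regions were present in smaller shares of the cells. The start of chromosome 7, 3000001 to 19123448, was lost in 20 of 47 cells (42.6%, 28.3 to 57.8) at -0.43 (SD 0.20). The start of chromosome 8, 3000001 to 20712178, was gained in 15 of 47 cells (31.9%, 19.1 to 47.1), and chromosome 13 from 21630440 to 31175104 was gained in 13 of 47 cells (27.7%, 15.6 to 42.6). The rest of chromosome 13, 32179806 to 120321639, was lost in 11 of 47 cells (23.4%, 12.3 to 38.0), and the end of chromosome 18, 77932880 to 90602639, was gained in 10 of 47 cells (21.3%, 10.7 to 35.7). T7 had a loss of the distal part of chromosome 10, 70187514 to 130594993, in 11 of 48 cells (22.9%, 12.0 to 37.3). The start of chromosome 14, 3000001 to 13448902, was called gained in 10 of 47 T1, 10 of 48 T7 and 21 of 50 T9 cells, but this region was no longer found in any tumour once 32 bins that departed alike in all tumours were left out. In all, T1 had 10 regions, T7 had 4 and T9 had 7. With the ratio taken from depth, T1 had 48 regions, T7 had 10 and T9 had 11, and with the stricter thresholds T1 had 4 and T7 had 2. Over 4806 autosomal bins, which are not independent, the departures of a bin from its surroundings had a Spearman rho with its number of genes of -0.18 in T1, -0.0036 in T7 and 0.01 in T9.

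The gained parts of chromosomes 8 and 13 in T1 held narrower windows with higher levels, which were chosen after the values were seen from 12 windows that the same scan gave. The others were T1 losses on chromosomes 2 (1 window), 4 (5) and 9 (2), of which 59812059 to 62391412 on chromosome 4 lay at -1 or lower in 14 of 47 cells, a T9 loss on chromosome 2 and a T7 gain on chromosome 14. The windows on chromosomes 2 and 14 were shifted in all 3 tumours, with levels of -1.08, -0.67 and -0.87 and of 0.64, 0.69 and 0.78 in T1, T7 and T9. The chromosome 4 window at 59812059 to 62391412 had levels of -0.90, -0.17 and -0.31 in T1, T7 and T9. Each lay lower than the level of the whole chromosome, which was -0.69, -0.04 and -0.20. On chromosome 13, a window of 6.03 Mb (25146896 to 31175104, 36 protein-coding genes, among them the transcription factor genes Sox4, E2f3 and Irf4) reached a log2 ratio of at least 1 in 12 of 47 T1 cells (25.5%, 13.9 to 40.3), at least 2 in 7 cells and at least 4 in 2 cells. Its levels ran from -0.39 to 4.43 over the T1 cells, the highest being 21.6-fold above the cell's typical level. On chromosome 8, a window of 7.91 Mb (7447887 to 15355241, 55 protein-coding genes, among them the insulin receptor substrate gene Irs2 and the collagen genes Col4a1 and Col4a2) reached at least 1 in 10 of 47 T1 cells (21.3%, 10.7 to 35.7) and at least 2 in 0 cells. Of the 47 cells, 8 reached 1 in both windows, 4 in the chromosome 13 window alone, 2 in the chromosome 8 window alone and 33 in neither. This split depends on the cut at 1. The 4 cells had the chromosome 8 window at 0.58, 0.78, 0.47 and 0.997, where the T1 median was 0.38. The 2 cells had the chromosome 13 window at 0.59 and -0.39. No T7 or T9 cell reached 1 in either window.

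**Figure D4:**
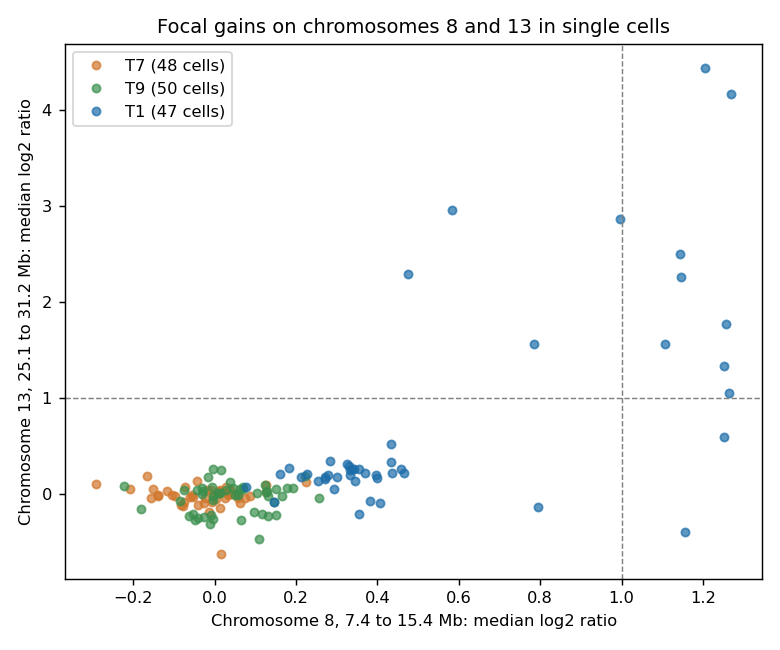
Median log2 ratio of the chromosome 13 window against that of the chromosome 8 window, 1 point per cell (47 T1, 48 T7 and 50 T9 cells), with dashed lines at 1. The T7 and T9 points lie between -0.63 and 0.26 on both axes, and 8 T1 cells lie above 1 on both axes, with the highest chromosome 13 level at 4.43.

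The fixed genes showed which loci these changes covered. A value is that of the bin and segment holding the gene, not of the gene alone. Gt(ROSA)26Sor, the Rosa26 locus (chromosome 6, 113067428 to 113077244), lay in a gained segment in 37 of 47 T1 cells, 36 of 48 T7 cells and 41 of 50 T9 cells, with levels of 0.46 (SD 0.14), 0.38 (SD 0.13) and 0.42 (SD 0.16). Trp53 (chromosome 11, 69580348 to 69591873) lay in a lost segment in 5 of 47 T1 cells, 1 of 48 T7 cells and 0 of 50 T9 cells, with levels of -0.20, -0.04 and 0.02. Under the stricter thresholds, the gain at the Rosa26 locus was called in 36% of T9 cells. The share for Trp53 in T1 was 0% with the ratio taken from depth. The engineered deletion within Trp53 is smaller than a bin and was not measured.

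Of the 16 lung adenocarcinoma oncogenes, 7 lay in a called segment in at least 20% of the cells of a tumour. Met, a receptor tyrosine kinase gene, and Braf, a kinase gene of the MAP kinase pathway, lie on proximal chromosome 6. Met was gained in 35 of 48 T7 cells at 0.38 but in 14 of 47 T1 cells at 0.20 and 2 of 50 T9 cells at 0.03, and Braf was gained in 36, 16 and 2 cells. Yap1, a transcriptional coactivator gene of the Hippo pathway, was gained in 44 of 50 T9 cells at 0.46 (SD 0.15) and had levels of -0.17 in T1 and -0.04 in T7. Nfe2l2, which encodes the oxidative stress factor NRF2, was gained in 35 of 48 T7 cells at 0.39. Mdm2, which encodes the ubiquitin ligase of p53, and Cdk4, a cell cycle kinase gene, were lost with chromosome 10 in 13 of 47 T1 and 11 of 48 T7 cells. Tert, the telomerase reverse transcriptase gene, was lost in 10 of 47 T1 cells. Met was gained in 47.9% of T7 cells with the ratio taken from depth, and Tert was then lost in 12.8% of T1 cells, and in 16% with the stricter cell filter, both under the criterion of 20%. The stricter thresholds brought Met and Braf to 18.8% and Nfe2l2 to 16.7% of T7 cells and Mdm2, Cdk4 and Tert to 2.13% of T1 cells, while Yap1 was gained in 58% of T9 cells.

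Of the 16 tumour suppressor genes, 9 met the same criterion, and they were not all lost. Cdkn2a, which encodes cell cycle inhibitors, and Arid1a, a chromatin remodeller gene, were each lost with chromosome 4 in 45 of 47 T1 cells, at -0.67 and -0.69, and in 7 of 50 T9 cells. Atm, a DNA damage kinase gene, was lost in 46 of 47 T1 cells at -0.64 and in 47 of 50 T9 cells at -0.63, and Setd2, a histone methyltransferase gene, in 45 of 47 and 47 of 50 cells at -0.64 and -0.62. Keap1, whose product restrains NRF2, and Smarca4, a chromatin remodeller gene, lie on the gained start of chromosome 9 and were each gained in 45 of 50 T9 cells at 0.47 (SD 0.15). Cdkn1b was gained with distal chromosome 6 in 37, 36 and 41 cells of T1, T7 and T9. Tsc1 was gained with chromosome 2 in 35 of 48 T7 cells, and Stk11 was lost with chromosome 10 in 13 of 47 T1 and 11 of 48 T7 cells. With the ratio taken from depth, the T1 losses of Arid1a and Stk11 fell under the criterion, at 12.8% and 17.02% of cells, and those of Atm and Setd2 were called in 63.8% and 48.9%, while that of Cdkn2a was called in 97.9%. With the stricter thresholds, losses in T1 were called in 36.2% of cells for Cdkn2a, 38.3% for Arid1a, 17.02% for Atm and Setd2 and 2.13% for Stk11, the gain of Tsc1 in 12.5% of T7 cells, and the gains of Keap1, Smarca4 and Cdkn1b in 60%, 62% and 40% of T9 cells.

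Of the 7 genes of alveolar type 2 identity, 2 met the criterion. Sftpb, a surfactant protein gene, was gained in 36, 36 and 39 cells of T1, T7 and T9, and Lyz2 was lost with chromosome 10 in 13 T1 and 11 T7 cells. Of the 11 genes of plasticity and mesenchymal state, 5 did. Slc4a11, Vim and Zeb2 were gained with chromosome 2 in 35 of 48 T7 cells, Hmga2 was lost with chromosome 10 in 13 T1 and 11 T7 cells, and Itga2 was lost in 10 T1 cells. The Itga2 loss was in 16% of T1 cells, under the criterion, with the stricter cell filter, and Zeb2 was gained in 41.7% of T7 cells with the ratio taken from depth. Under the stricter thresholds, Vim, Zeb2 and Slc4a11 were gained in 12.5%, 16.7% and 22.9% of T7 cells, Hmga2, Lyz2 and Itga2 were lost in 2.13% of T1 cells, and Sftpb was gained in 36% of T9 cells. Over all 53 fixed genes, 25 met the criterion. T1 had 6 gained and 11 lost, T7 had 11 gained and 5 lost, and T9 had 7 gained and 2 lost. With the looser thresholds 40 genes met it, and with the stricter thresholds 13 did. The share of all bins that met it was not counted. The counts therefore do not show that the listed genes were changed more often than others.

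The share of the autosomal genome in called segments had a median of 16.96% in T1 (SD 10.1, range 8.91 to 50.8), 13.1% in T7 (SD 6.60, 0 to 29.6) and 11.3% in T9 (SD 5.88, 0 to 37.9). T1 cells carried a median of 5.31% gained and 11.6% lost. In T7 the median gained share was 13.1% and the median lost share 0%, and in T9 they were 5.62% and 4.83%. The ranges of the 3 tumours overlapped. With the ratio taken from depth the T1 median was 36.3%, and with the stricter thresholds the medians of T1, T7 and T9 were 7.97%, 0% and 3.65%.

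Copy number profiles were then compared between cells to ask whether they separated the tumours. The best correlated cell over the 19 chromosome medians came from the same tumour for 138 of 145 cells (95.2%, 90.3 to 98.0), where random pairing gives 32.9%. The match was within the tumour for 47 of 47 T1, 47 of 48 T7 and 44 of 50 T9 cells. The median correlation between pairs of cells was 0.78 within T1, 0.69 within T7 and 0.58 within T9. Between tumours it was 0.34 for T1 and T7, 0.50 for T1 and T9, which shared the loss of distal chromosome 9, and 0.32 for T7 and T9. With the weighted mean over bins the order turned for T9, with 0.44 within T9 and 0.45 between T1 and T9.

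Within each tumour, cells differed in their set of called autosomes. The most common set in T1 was loss of chromosomes 4 and 9 with gain of chromosome 6, in 21 of 47 cells (44.7%, 30.2 to 59.9). In T7 it was gain of chromosomes 2 and 6, in 19 of 48 cells (39.6%, 25.8 to 54.7), and a further 8 cells carried this pair with loss of chromosome 10. In T9 it was a call of loss on chromosome 9 and on no other autosome, in 20 of 50 cells (40%, 26.4 to 54.8). Another 5 cells were called with loss of chromosome 9 and gain of chromosome 6. Sets rest on the median of a whole chromosome and leave out changes of a part of it. In T9, the gained start of chromosome 9 (45 of 50 cells) and the lost end of chromosome 11 (44 of 50) thus go uncounted. T1 had 24 distinct sets, 21 of them in 1 cell each, T7 had 12 with 7 in 1 cell, and T9 had 17 with 12 in 1 cell. No autosome was called in 0 T1 cells, 8 T7 cells and 7 T9 cells. Such cells can still hold called segments or levels near a threshold. Among those of T9, cell 180124 had 27.0% of its autosomal genome in called segments, and cell 180111 had 0%. Chromosome 9 of cell 180124 lay at -0.414, against the threshold of -0.415. With the stricter thresholds, cells with no called autosome made up 36.2% of T1, 77.1% of T7 and 96% of T9. With the looser thresholds they made up 4.17% of T7 and 2% of T9, and with the weighted mean over bins 60% of T9. Distinct sets numbered 43 in T1 and 34 in T9 with the looser thresholds, and 12, 7 and 3 in T1, T7 and T9 with the stricter ones.

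Changes present in part of a tumour were then compared cell by cell. Gains of chromosomes 2 and 6 occurred together in 33 of 48 T7 cells, with 1 cell having chromosome 2 alone, 4 having chromosome 6 alone and 10 having neither. This split depends on the gain threshold of 0.322. Of the cells with neither, 180089 and 180099 had chromosome 2 at 0.320 and 0.306 and chromosome 6 at 0.319 and 0.301. Cells 180063 and 180084 lay at 0.01 on chromosome 2 and -0.01 on chromosome 6. In T1, the gained start of chromosome 8 and the gained part of chromosome 13 occurred together in 13 of 47 cells, with 2 cells having the former alone, 0 the latter alone and 32 neither. These are the wider regions, called at the gain threshold, and not the narrower windows counted at a log2 ratio of 1. Loss of chromosome 10 accompanied the chromosome 8 gain in 11 T1 cells, with 4 having the gain alone, 2 the loss alone and 30 neither. Loss of distal chromosome 13 and loss of chromosome 10 were found together in 10 T1 cells, with 3 having the chromosome 10 loss alone and 0 the chromosome 13 loss alone. The loss at the start of chromosome 7 and the gain of chromosome 8 occurred together in 4 T1 cells, with 16 having the former alone, 11 the latter alone and 16 neither. Loss of chromosome 10 and gain of chromosome 6 overlapped in 10 T1 cells, with 3 having the loss alone.

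X lay at -0.25 (SD 0.12) in T1, -0.02 (SD 0.13) in T7 and -0.15 (SD 0.19) in T9, relative to the autosomes of the same cells. It was called lost in 3 of 47 T1 cells (6.38%, 1.34 to 17.5), 2 of 48 T7 cells (4.17%, 0.509 to 14.3) and 7 of 50 T9 cells (14%, 5.82 to 26.7). Taken from depth, X lay at -0.39, 0.10 and 0.03 in T1, T7 and T9. The reference behind the deposited ratio, and whether it removes a difference between sexes, is not given in the sources used here. An X level of that ratio therefore gives no number of copies. Depth uses no reference, though it lacks the correction by bin. In depth, X of T7 and T9 lay near the autosomal level and not near -1, the step of 1 copy against 2. X of T1 lay lower than X of T7 and T9 in both measures.

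Noise between neighbouring bins was compared with depth over all 150 cells as a check of the libraries, in 8 relations adjusted together by Benjamini-Hochberg. Only the rank correlation within T7 passed, with a Spearman rho of -0.46 (permutation p = 0.00079, adjusted 0.0063) and -0.46 again without the 2 cells farthest from the median depth. The Pearson r in T7 was -0.34 (permutation p = 0.02, adjusted 0.08) and -0.25 without those 2 cells. In T1 the Pearson r was -0.10 (permutation p = 0.51, adjusted 0.68; -0.13 without 2 cells) and rho -0.03 (permutation p = 0.85, adjusted 0.88). In T9 they were 0.02 (permutation p = 0.88, adjusted 0.88; -0.20 without 2 cells) and -0.13 (permutation p = 0.35, adjusted 0.57). Pooled over tumours, which overlapped in depth, r was -0.18 (permutation p = 0.037, adjusted 0.099; -0.20 without 2 cells) and rho 0.10 (permutation p = 0.21, adjusted 0.42). Median noise was 0.19 in T1, the most deeply sequenced tumour, 0.15 in T7 and 0.13 in T9. The pooled values thus also take in differences between tumours.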

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

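All tests in this part were chosen after the result was seen, including the bounds for an intermediate level and the choice of chromosome 4 and of the windows.

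The Y bins, which no comparison used, had depth above 0 in all 3 tumours, and no control cells were analysed here. Their depth was 4.22% of the autosomal depth in T1, 9.66% in T7 and 10.9% in T9, and 99.8%, 99.9% and 99.98% of the Y values of single bins and cells were above 0. X bins had 76.6%, 107.0% and 102.1% of the autosomal depth in the same tumours. The Y depth lay far below the autosomal depth, and a depth above 0 does not by itself show that a Y chromosome was present.

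Chromosome 4 of T9 lay between the flat level and the loss threshold, from -0.12 down to -0.42, in 36 of 50 cells (72%, 57.5 to 83.8), with a median of -0.20 (SD 0.17), and chromosome 19 did so in 30 of 50 cells (60%, 45.2 to 73.6) at -0.21 (SD 0.20). A bias with gene density would pull the gene-richest autosome, chromosome 7, down in the same way, but its median in T9 was 0.030. Random pairs of cells in 1 well, with and without a loss, can give an intermediate level in at most 50% of wells, and the lower bound of 57.5% for chromosome 4 lies above that, although the bound of 45.2% for chromosome 19 does not. Genome doubling followed by loss of 1 of 4 copies, a hypothesis, may give such a level. The value predicted from distal chromosome 9 was -0.27, within 1 SD over cells of the observed -0.20. That SD is a spread between cells and not the error of the median, so the comparison decides nothing. Doubling and other causes cannot be told apart, because centring hides the number of copies of the whole genome.

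The chromosome 13 window of T1 differed between cells by several doublings, with 7 of 47 cells at a log2 ratio of 2 or more and a range of -0.39 to 4.43, while the chromosome 8 window did not exceed 1.27. Mapping errors or repeats would also raise these bins in the other tumours, where the highest value in any T7 or T9 cell was 0.26. Noise of single libraries would raise other windows of the same number of bins in T1. Outside the chromosome 8 and 13 windows, 0.0386% of 18142 values (7 values) reached 1, against 25.5% of cells here. That contrast is partly fixed by the choice. The window was chosen because at least 10% of T1 cells reached 1, and gains found by the same rule were left out of the other values. Extra copies outside the chromosome that divide unequally between daughter cells may give such a spread and remain a hypothesis, with 7 cells at 2 or more. They cannot be told apart from repeated copies within the chromosome, since the position of the copies was not measured.

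Some bins departed from their surroundings in the same direction in all 3 tumours. The end of chromosome 2, 174999822 to 178191768, had levels of -1.08 in T1, -0.67 in T7 and -0.87 in T9 and lay past the loss threshold in at least 93.8% of the cells of each tumour, and the start of chromosome 14, 3000001 to 7478101, had levels of 0.63, 0.68 and 0.76. Predicted genes with Gm symbols made up 74.7% and 91.7% of the listed genes there, against 43.3% in all bins. These bins were chosen for departing alike in all 3 tumours, so the share of 93.8% was fixed by the choice and tests nothing. A mapping or strain difference from the reference and an inherited copy number difference of the mouse, which would also give the T7 level of -0.67, cannot be told apart, because no normal cells were analysed here.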

How the results depend on the processing

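The bin filter without bins alike in all tumours, and mode centring for the share of flat autosome levels, were chosen after seeing the data, and the other alternatives were planned. Of 316 comparisons of the results for tumours with their values under an alternative, 259 were counted as staying and 52 as moved. A further 3 newly passed the test, 1 no longer passed and 1 reversed. Staying meant within the exact interval for shares and on the same side of the threshold for the noise tests. For the altered genome, X levels and correlations, it meant a shift smaller than the SD over cells or pairs of cells. That SD is a spread and not an error, and counts of regions, sets and genes could change by a limited factor. The T9 correlation of 0.44 with the weighted mean, against 0.58 in the main results, thus counted as staying. Of 312 comparisons at single genes, 271 stayed and 41 moved. So counted, none of the results compared moved with all cells, all finite bins or a penalty factor of 10. The same held for segments of at least 5 or 20 Mb and for the removal of alike bins. This removal still ended the chromosome 14 region in all tumours. It also gave T1 a gain of chromosome 8 from 113757741 to 129301213 in 10 of 47 cells. Depth limits what a single bin of a cell shows, but no correlation of noise between neighbouring bins with depth passed in T1 or T9, and the limit that depth sets on the calls was not tested. Where no construction is named, the cause was not tested.

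With looser thresholds, chromosomes 4 and 9 were lost in 100% of T1 cells and chromosome 9 in 92% of T9 cells, and chromosome 6 was gained in 93.6%, 91.7% and 82% of T1, T7 and T9 cells. The altered genome was 37.4% in T1 and 20.1% in T9, regions numbered 19 and 14, distinct sets 43 and 34, cells with no called autosome made up 4.17% of T7 and 2% of T9, and 40 fixed genes met the criterion. By the construction of the thresholds, more changes are called and fewer cells have none.

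With stricter thresholds, losses of chromosomes 4, 9 and 10 were called in 40.4%, 2.13% and 2.13% of T1 cells, loss of chromosome 9 in 0% of T9 cells, gain of chromosome 2 in 16.7% of T7 cells and gain of chromosome 6 in 25.5%, 20.8% and 4% of T1, T7 and T9 cells. The altered genome was 7.97% in T1, 0% in T7 and 3.65% in T9, regions numbered 4 in T1 and 2 in T7, distinct sets 12, 7 and 3 in T1, T7 and T9, cells with no called autosome 36.2%, 77.1% and 96%, and 13 fixed genes met the criterion.

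With the ratio taken from depth, chromosome 9 was lost in 72.3% of T1 and 48% of T9 cells, the altered genome of T1 was 36.3%, X lay at -0.39, 0.10 and 0.03 in T1, T7 and T9, and regions numbered 48, 10 and 11 in T1, T7 and T9. At single genes, shares moved for losses of Arid1a (12.8%), Atm (63.8%), Setd2 (48.9%) and Trp53 (0%) in T1 and gains of Met (47.9%) and Zeb2 (41.7%) in T7. This ratio lacks the authors' correction by bin. Centring on the mean gave loss of chromosome 9 in 64% of T9 cells, and centring on the mode gave gain of chromosome 6 in 38.3% of T1 and 8% of T9 cells. With the weighted mean over bins, chromosome 6 was gained in 10% and chromosome 9 lost in 0% of T9 cells, and 60% had no called autosome, while the correlation within T9 was 0.44, under the 0.45 between T1 and T9. A mean averages the gained and lost parts of chromosome 9 in T9 by construction. The stricter cell filter left 13 distinct sets in T1 and 2 regions in T7 and brought the T1 losses of Tert and Itga2 to 16% of cells, regions in at least 10% of cells numbered 19 in T1 and 15 in T9, and smoothed bins placed the best match within the tumour for 99.3% of cells.

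With the standard deviation of all bins as the noise, which also holds copy number changes, the pooled rho with depth was 0.27 (permutation test, adjusted p = 0.0059), the T7 Pearson r -0.34 (0.038), the T9 Pearson r 0.43 (0.0059) and the T9 rho 0.42 (0.0059), which had been -0.13, and these passed the threshold. Without the 2 cells farthest from the median depth they were 0.25, -0.10, 0.39 and 0.36, so the T7 r rests on those cells. The T7 rho of -0.25 (0.12) no longer passed, and the T1 rho was 0.03 (0.97). Cells were permuted across tumours for the pooled values, so these also take in differences between tumours. No paired analysis was possible because each cell belongs to 1 tumour and the cell numbers pair no cells.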

Other observations

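The scan for departures of single tumours in this part was made after a step on chromosome 9 had been seen in the T9 profile.

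Within the gained start of chromosome 9 in T9, a stretch of 1.49 Mb (35807085 to 37299936, 3 bins) lay higher still, at 0.91 (SD 0.22) against 0.48 in its surroundings. It lay at least 0.35 above the surroundings in 43 of 50 cells, a count that the choice of bins by their T9 median partly fixes. The same bins lay at -0.73 (SD 0.19) in T1 and -0.10 (SD 0.17) in T7. They hold 18 protein-coding genes, among them Chek1, which encodes a checkpoint kinase of the DNA damage response, Ei24, a p53-induced gene, and Stt3a, which encodes a subunit of the oligosaccharyltransferase. The scan looked for bins with a median at least 0.35 from the running median of 31 bins in 1 tumour and under 0.20 in the others. It found 100 runs in 112 bins of T1, 0 in T7 and 5 in 7 bins of T9, and 2 T1 runs and 1 T9 run had 3 bins or more. The T1 runs of that size were a rise on X (31104766 to 32327543, 0.31 against -0.37 around it, 42 of 47 cells) and a dip on chromosome 8 (3494210 to 4976838, -0.10 against 0.30, 32 of 47 cells), and they belong to a profile that is uneven along the genome in T1 throughout, with an SD of the departures of 0.17 over autosomal bins against 0.08 in T7 and T9. Over the same 4806 bins, departures had a Spearman rho with the number of genes in the bin of -0.18 in T1, -0.0036 in T7 and 0.01 in T9.

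T1 carried a ladder of levels beyond its called chromosomes. Chromosomes 3 and 12 lay between the flat level and the gain threshold in 40 and 42 of 47 cells, with medians of 0.18 (SD 0.10) and 0.19 (SD 0.08). Chromosomes 15, 11 and 7 lay between the flat level and the loss threshold in 37 (78.7%, 64.3 to 89.3), 34 (72.3%, 57.4 to 84.4) and 32 (68.1%, 52.9 to 80.9) of 47 cells, with medians of -0.18 (SD 0.10), -0.19 (SD 0.15) and -0.19 (SD 0.15). In T7 the same chromosomes had medians between -0.04 and -0.02. Of all autosome levels in T1 cells, 18.8% were flat, against 81.5% in T7 and 61.8% in T9. These shares depend on the centring, and with centring on the mode, an alternative chosen after seeing the data, they were 34.6%, 82.4% and 63.4%. Over the 19 autosomes, which are not independent, the Spearman rho of the median level with genes per Mb was -0.32 in T1, -0.16 in T7 and -0.05 in T9, and no explanation of the T1 levels was tested.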
